A study of Bos taurus with 106 samples.

How the data were processed

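Hepatic transcripts were measured in 8 Holstein cows, 4 per feeding level, on 2-colour spotted cDNA arrays. Per the labels, each liver cDNA was hybridised together with a reference made from a mixture of tissues that left out liver, slides were read on a Scanarray 4000, and images were processed with GenePix 4.0. The authors deposited a value per spot on a log2 scale, the ratio of Cy5 over Cy3, for 16416 spots on each of 106 arrays. Background correction, spot filters and normalization were not given in the sources used here. Array medians lay between -1.69 and 1.80, so the arrays had not been centred. The log base was taken from the values: exact values of 1 and -1 occurred 3.37 and 6.96 times as often as neighbouring values, the value 1.585 (log2 of 3) occurred 2.38 times as often, and 0.5 occurred 0.954 times as often. Spot intensities and signal over background were not given in the sources used here.

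Groups, days and cows were taken from the labels. The dye of each liver sample was taken from the titles, because the longer text of 4 arrays named the opposite dye. Arrays of opposite orientation had a median correlation over spots of -0.549. Arrays of the same orientation had a median of 0.741 and a lowest value of 0.315. Both arrays of a cow-day correlated negatively as deposited in 53 of 53 cow-days, with r from -0.803 to -0.0902, so the direction of each ratio followed the dyes. Every cow-day had 2 arrays, which were treated as a technical dye swap and counted as 1 sample.

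The value table held 8208 elements, more than the design text of the series states, and which elements account for the difference was not given in the sources used here. The 2 spots of each element were averaged (their correlation had a median of 0.900 over arrays). Each array was turned to liver over reference and centred on its median, and both orientations of a cow-day were averaged. A value was missing for 21368 spots, or 1.23%, and for 71 to 730 spots per array. An element was tested where at least 2 cows in each of the 14 groups had a value, which left 8061 elements and excluded 147. A complete set of values was available for 7577. The number of cows limits the precision, and counting depth does not apply to arrays.

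The analysis used limma 3.58.1 with statmod 1.5.0 in R 4.3.3. Days were compared in a fit of 14 diet-by-day group means with cow as a random block, because the cow labels pair samples across days. The estimated correlation within cows was 0.0176. Diets were weighted equally in comparisons of days. The 3 main diet comparisons used 1 value per cow: the mean of days -30 and -14, the mean of days 1, 14 and 28, and the difference between these means. The tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and an adjusted threshold of 0.05. The design, the gene lists, the rule for named genes and 17 of the 18 comparisons were fixed before the data were examined.

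Gene symbols came from the platform annotation given with the series, updated through a RefSeq gene table of assembly ARS-UCD2.0. A single symbol was available for 5598 elements (5530 of them tested), several symbols for 95 and none was listed for 2515. The 5598 elements carried 4452 distinct symbols, and 5591 of their gene identifiers were found in the gene table. No genome build was given for the array, and no coordinates are printed. A cDNA element may also hybridise to transcripts of related genes, and the text says where another element of a named gene that passed had the opposite sign in a comparison of days or diets.

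Named genes followed this rule: among elements with 1 symbol that passed, up to 10 with the largest increase and up to 10 with the largest decrease. For each gene list described, up to 4 members with the smallest p were added. PC, CPT1A, ACSL1 and SREBF1 were followed in each comparison whatever their result, as the members of a list of liver metabolism genes that the array carried. Where nothing passed, up to 5 elements in each direction with the smallest p are given as values. Gene lists with at least 5 measured members (26 lists) were tested with cameraPR on the moderated t at a preset correlation of 0.01, with a correlation estimated per list, and with fry. Each gene was represented by a single element. The direction of cells or pathways was also counted with adjustment over the list alone.

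The fits were tested on simulated values with the real design, missing values and spread of each element. The noise was drawn independently for each element and cow-day, with the same spread on all days. In the real values 2 shared components held 28.1% and 18.3% of the variance within groups. The false calls given here therefore apply to independent noise only. For day 28 against day -14, 37% of 100 elements changed by 0.5 on the log2 scale and 90% of 100 changed by 1 were recovered. Among the unchanged of the 8061 elements there were 9 false calls. For the diet comparison after calving the shares were 39% and 91%, with 4 false calls among the unchanged of the 8059 elements. A simulated component shared by all elements and uneven between the diets gave 5065 calls without component covariates and 0 with them. In the same kind of simulation, 200 independent changes gave 134 calls without the covariates and 119 with them. The noise in the simulated component was lowered after a first version gave no calls.

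Other settings fixed before the files were opened were no centring, quantile and scale normalization, other filters on missing values, each dye orientation alone, an average per gene, array weights, trend and robust moderation, other treatments of cow, other choices of days, leaving out each cow, an estimated list correlation and fry. Further settings were chosen after seeing the data: the correlation of both orientations as a covariate, scores on 2 within-group components as covariates, a loess on a rank that stands in for intensity, cow as a fixed block, leaving out cow-days whose orientations correlated under 0.6, single days within the diet means, and most list counts under other settings. The component scores were chosen once the second component was seen to follow the diet difference on days 1 and 14. The comparison of days 28 and 49 with days -65 and -30 was also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.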

Results

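Hepatic transcript abundance was followed in 8 Holstein cows through a dry period of 65 days and into lactation, to compare 2 planes of nutrition before calving. The diet of all cows had a moderate energy density (1.60 Mcal/kg). Intake was limited to about 80% of the NRC requirement in 4 cows, and 4 cows ate freely and reached about 120%. Liver was sampled on days -65, -30, -14, 1, 14, 28 and 49 relative to calving. The 53 cow-days comprised 7 cows on day -65, 6 cows on day 49 and 8 cows on each other day. The ad libitum group lacked 1 cow on day -65 and 2 cows on day 49. Each sample was hybridised in both dye orientations against a reference of other tissues, and 8061 elements were tested as log2 ratios of liver over reference.

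Both dye orientations of a liver sample gave closely related profiles on days -65, -30, 28 and 49 and less closely related profiles on days -14, 1 and 14. The correlation across elements averaged 0.852 ± 0.046 (SD, n = 7) on day -65, 0.886 ± 0.027 (SD, n = 8) on day -30, 0.863 ± 0.030 (SD, n = 8) on day 28 and 0.897 ± 0.034 (SD, n = 6) on day 49. It averaged 0.668 ± 0.126 (SD, n = 8) on day -14, 0.616 ± 0.188 (SD, n = 8) on day 1 and 0.669 ± 0.138 (SD, n = 8) on day 14. The 7 cow-days with a correlation under 0.6 fell on days -14, 1 and 14. Averaged per cow, the correlation on those 3 days was lower by 0.223 than on the others, in 8 of 8 cows (exact sign flips, p = 0.0078, the smallest that 8 cows allow, adjusted p = 0.0273 over 7 tests of array quality). The day sets of these tests were picked after the values had been seen. On days -14, 1 and 14 the mean was 0.585 in ad libitum and 0.717 in restricted cows (exact permutation p = 0.229, adjusted p = 0.267), and on days -30 and 28 it was 0.860 and 0.888 (exact permutation p = 0.114, adjusted p = 0.2). The slope of strong elements on their mean was also lower on the 3 days, by 0.104 in 8 of 8 cows (exact sign flips, p = 0.0078, adjusted p = 0.0273). After centring, elements with little spread on the other days were still shifted between ad libitum and restricted cows by 0.107 on days -14, 1 and 14 (exact permutation p = 0.143, adjusted p = 0.2), by 0.146 on days 1 and 14 (exact permutation p = 0.0286, adjusted p = 0.0667) and by -0.0028 on days -30 and 28 (exact permutation p = 0.829, adjusted p = 0.829). Those elements were picked for little spread on days -65, -30, 28 and 49. A shift near 0 on days -30 and 28 therefore follows largely from that choice. Each comparison that sets days -14, 1 and 14 against the others also compares samples of different technical agreement.

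**Figure D1:**
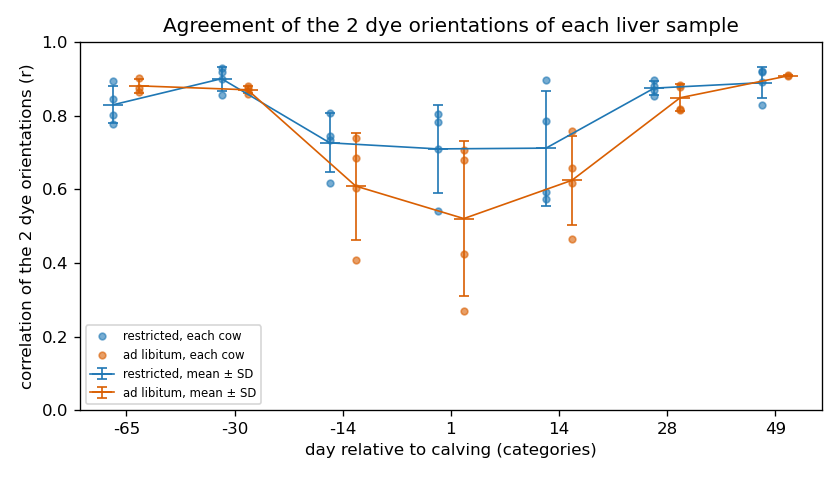
Correlation across elements between the 2 dye orientations of each liver sample (vertical axis, r) by day relative to calving (horizontal axis, spaced as categories). Points are cows, and horizontal marks with bars are the mean and SD of each diet. The day means are 0.668, 0.616 and 0.669 on days -14, 1 and 14 and 0.852 to 0.897 on the other days.

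Among elements with a gene symbol, H2B, a core histone, had the smallest p over the 7 days, with mean log2 ratios of -1.87 ± 0.20 (SD, n = 7) on day -65 and -2.05 ± 0.18 (SD, n = 8) on day -30. Its means were 0.03 ± 0.22, -0.16 ± 0.27 and -0.37 ± 0.76 (SD, n = 8) on days -14, 1 and 14, and -2.16 ± 0.35 (SD, n = 8) and -1.99 ± 0.15 (SD, n = 6) on days 28 and 49. SLC10A1, the sodium-dependent bile acid transporter of hepatocytes, took the opposite course, with means of 6.08, 5.65, 4.26, 3.86, 4.66, 6.14 and 5.84 over the 7 days. EMP1, LAMA5, PLEKHM2, SIPA1L1, FOSL2, MSL1 and MAPRE2 were higher on days -14, 1 and 14 than on the other days, and TRANK1 was lower. The limma F test over days passed for 3497 elements, and 4093 had an unadjusted p under 0.05. With the agreement of the orientations as a covariate, a setting chosen after seeing the data, 1491 elements passed.

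Comparing day -14 with day -65 asked how the liver changed over the dry period. TNC, the matrix protein tenascin C, rose by 2.26 ± 0.25 (SE) on the log2 scale, from -2.77 ± 0.39 (SD, n = 7) to -0.49 ± 0.39 (SD, n = 8), in 7 of 7 cows with both days (adjusted p = 7.22e-09). SIPA1L1 rose by 3.02 ± 0.26 (SE), from -0.23 ± 0.43 (SD, n = 7) to 2.75 ± 0.47 (SD, n = 8). FSTL3, EMP1, MGC127133, COL3A1, CD109, H2B, LAMA5 and MMP2 rose by 1.81 to 2.17. The steepest decreases were those of CD80, an immune costimulatory molecule (-2.22 ± 0.33), LOC616364 (-2.17 ± 0.24) and SLC10A1 (-1.82 ± 0.21). The iron carrier TF fell by 1.45 on the log2 scale (SE 0.16), and TRANK1, RASSF6, SERPINA3-3, CA2, CD5L and KDR fell by 1.46 to 1.69. In all, 1445 elements rose and 1114 fell among 8061. The balance of directions rested on the centring: without it 3815 passed and 98.4% of them were higher.

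Of 45 ribosomal protein genes 39 rose at day -14 and none fell (41 rose when adjusted over the list alone), among them RPS27 (1.54 ± 0.16), RPS29 (1.43 ± 0.15) and RPL39 (1.14 ± 0.15). The camera test gave adjusted p = 8.99e-22 with the preset correlation, and adjusted p = 0.118 with an estimated correlation. Of 18 extracellular matrix genes 12 rose and none fell (12 when adjusted over the list alone), with camera adjusted p = 3.43e-06, and adjusted p = 0.274 with an estimated correlation. Beside MMP2, named above, they included FBLN1 (1.49 ± 0.17), COL6A1 (1.47 ± 0.20) and TIMP1 (1.16 ± 0.22). Markers of stellate cells and fibroblasts moved the same way, 5 of 7 up (5 when adjusted over the list alone), with THY1 at 0.48 ± 0.09 and DCN at 0.89 ± 0.26 (adjusted p = 0.0204, and 0.52 with an estimated correlation). Glycolysis genes did so for 6 of 14 (7 up and 1 down when adjusted over the list alone), including ALDOA (1.37 ± 0.22), PFKP (0.45 ± 0.10) and TPI1 (0.62 ± 0.19), with adjusted p = 0.0204, and 0.597 with an estimated correlation. HK1 was at 0.79 ± 0.14, and its second element passed in the opposite direction.

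Of 8 endothelial markers 4 fell and none rose (4 when adjusted over the list alone), with CDH5 at -1.11 ± 0.24, LYVE1 at -0.76 ± 0.24 and PECAM1 at -0.55 ± 0.10, although a second PECAM1 element rose (adjusted p = 0.0135, and 0.118 with an estimated correlation). The endothelial list represents KDR by its other element, at -0.61 ± 0.16. Of 10 complement genes 4 fell and none rose (4 when adjusted over the list alone), SERPING1 (-1.44 ± 0.22), C1R (-0.75 ± 0.17), C1S (-0.95 ± 0.22) and C2 (-0.71 ± 0.19), with adjusted p = 0.0135, and 0.52 with an estimated correlation. Without centring the complement median was 0.14 and therefore above 0, while the median of all elements was 0.54, so the list stayed below the other elements. Among the metabolism genes PC, which makes oxaloacetate for gluconeogenesis, rose by 0.42 ± 0.14 (adjusted p = 0.0196), in 4 of 7 cows with both days. Its mean rose only in restricted cows, from -0.50 ± 0.21 to 0.62 ± 0.30 (SD, n = 4). In ad libitum cows it went from 0.28 ± 0.20 (SD, n = 3) to 0.02 ± 0.29 (SD, n = 4). CPT1A, ACSL1 and SREBF1 did not pass, with values of 0.41 and -0.21 for the 2 CPT1A elements. With the agreement covariate 1524 elements passed in this comparison, and leaving out cow 7187 left 1459.

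**Figure D2:**
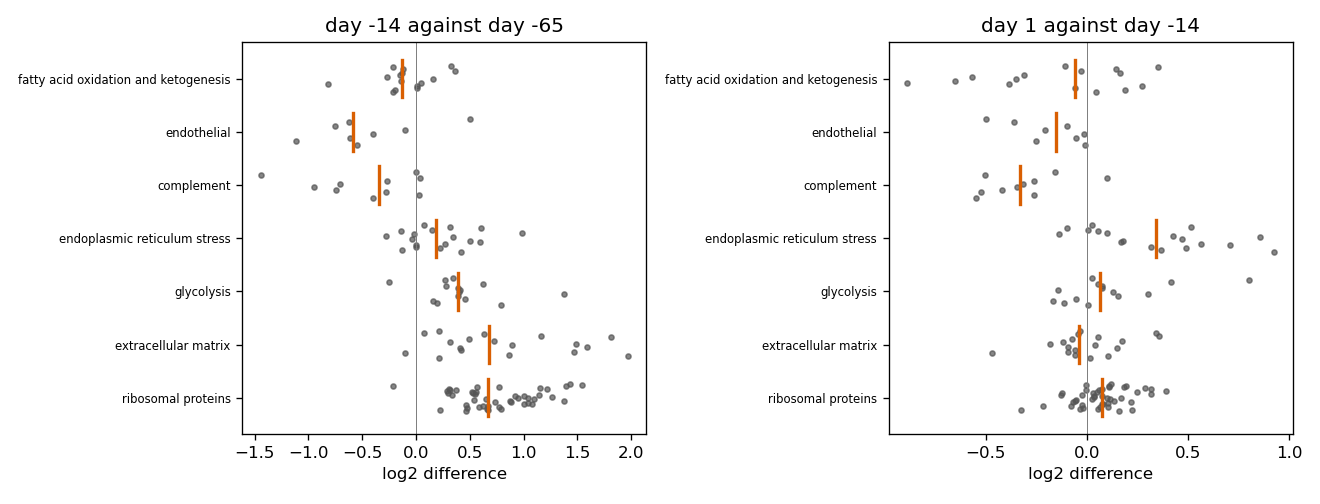
Log2 differences of the measured members of 7 gene lists (rows) for day -14 against day -65 (left) and day 1 against day -14 (right). Points are single genes and orange bars are list medians. In the left panel ribosomal, matrix and glycolysis genes lie mostly above 0 and endothelial and complement genes mostly below 0, and the complement median turns positive there without centring.

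Across calving, day 1 against day -14, changes were fewer. GPX3, a secreted glutathione peroxidase, rose by 2.98 ± 0.66 (SE) on the log2 scale, from 2.16 ± 2.21 (SD, n = 8) to 5.14 ± 1.24 (SD, n = 8), in 7 of 8 cows (adjusted p = 0.031). SSR3, a translocon-associated subunit of the endoplasmic reticulum, rose by 0.97 ± 0.15 (adjusted p = 0.000574) and DNAJB11, a chaperone cofactor, by 0.86 ± 0.20 in 8 of 8 cows (adjusted p = 0.035). S100A12, a calcium-binding protein of neutrophils, rose by 0.87 ± 0.20. WWC3, ANP32E, PRDX4, TSPAN13, PDHA1 and MSX1 rose by 0.59 to 0.90, while another WWC3 element had the opposite sign and did not pass. CAT, the peroxisomal catalase, fell by 0.83 on the log2 scale (SE 0.19), in 6 of 8 cows, and FBLN2, LGMN, HEYL, RNF5 and LOC613570 fell by 0.48 to 0.79.

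Of 18 endoplasmic reticulum stress genes DNAJB11 rose, 4 rose when adjusted over the list alone, and none fell, with P4HB at 0.56 ± 0.16 and PDIA6 at 0.71 ± 0.24 not passing over all elements (camera adjusted p = 9.24e-06, and 0.0784 with an estimated correlation). Cytochrome P450 and conjugation genes lay lower as a group, with 0 of 5 passing and 3 falling when adjusted over the list alone (adjusted p = 0.00652, and 0.0784 with an estimated correlation), and SULT1A1 was at -0.64 ± 0.22. Of 10 complement genes 0 passed, also when adjusted over the list alone, with SERPING1 at -0.50 ± 0.21 (adjusted p = 0.00175, and 0.24 with an estimated correlation). Markers of T and NK cells (0 of 8) and of macrophages (0 of 12) also lay lower, with 1 each falling when adjusted over the list alone (adjusted p = 0.00716 and 0.034, and 0.24 and 0.395 with an estimated correlation). Chaperone (0 of 16) and oxidative phosphorylation genes (0 of 40) lay higher, and iron and heme (0 of 7), urea cycle (0 of 10) and cholesterol genes (0 of 7) lay lower, with preset adjusted p from 0.00652 to 0.0318 and estimated ones from 0.101 to 0.395. When adjusted over the list alone, 1 iron and heme gene and 1 urea cycle gene fell and 0 passed in the other 3 lists. PC was at 0.32 ± 0.14 and did not pass.

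Among 8061 elements 24 were higher and 8 lower at day 1 than at day -14 by limma, and 795 had an unadjusted p under 0.05. No element passed without centring, with the liver in Cy3 alone or without the cow-days of low orientation agreement, and the count was 3 without cow 6952 and 96 without cow 6877. Both days belong to the set with poorer agreement of the orientations.

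**Figure D3:**
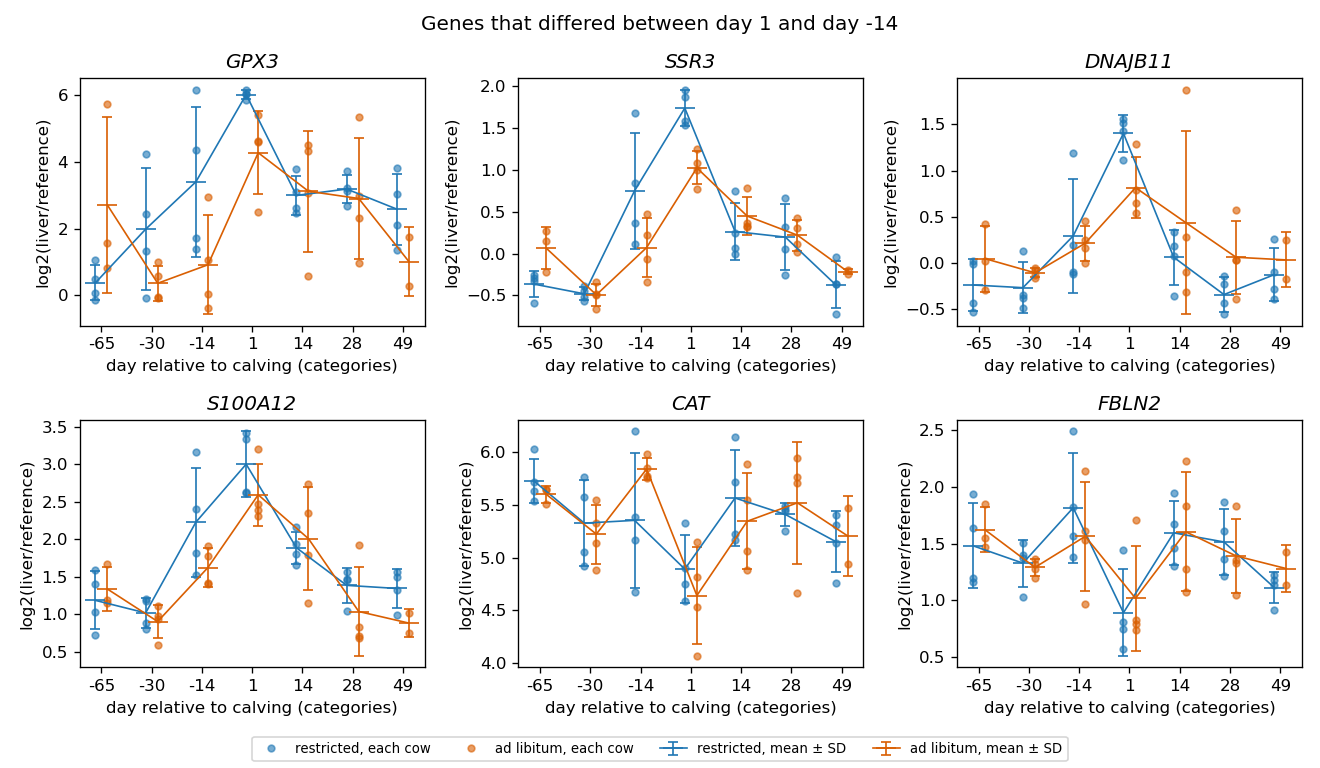
Log2 ratios of liver over reference (vertical axes) by day relative to calving (horizontal axes, spaced as categories) for 6 genes that differed between day 1 and day -14. Points are cows, and horizontal marks with bars are the mean and SD of each diet. GPX3 had a mean of 2.16 on day -14 and 5.14 on day 1, and CAT fell from 5.60 to 4.77.

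By day 14 of lactation no single gene differed from day -14 by limma. The smallest p among decreases belonged to SPIRE1 (-0.60 ± 0.12, adjusted p = 0.0805), followed by RETREG1 (-0.77 ± 0.17), CCK, CELF2 and MAN2A2 (-0.89 ± 0.22). Among increases ECT2, TOR1B, AKAP12, GALNT6 and SLC36A2 had values between 0.38 and 0.54. Of the 18 extracellular matrix genes 0 passed, also when adjusted over the list alone, although the list lay lower (camera adjusted p = 0.0118, and 0.856 with an estimated correlation), with DCN at -0.61 ± 0.25 and COL6A1 at -0.41 ± 0.19. An unadjusted p under 0.05 was reached by 728 elements. Leaving out cow 6877 gave 274 elements.

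Days 28 and 49 were compared with day -14, whose samples also enter the comparison with day -65, so opposite signs in these comparisons arise partly from the shared samples. TNC fell by 2.36 on the log2 scale at day 28 (SE 0.24, 8 of 8 cows, adjusted p = 1.78e-09) and by 2.43 at day 49. SIPA1L1 (-2.10 ± 0.25), H2B (-2.19 ± 0.17), LAMA5 (-1.90 ± 0.17) and FSTL3 (-1.90 ± 0.26) fell with it at day 28, as did ITPK1, ID1, EMP1, H1-3 and CD109 by 1.61 to 1.92. CD80 rose by 2.48 ± 0.32 at day 28 and 2.45 ± 0.36 at day 49, and SLC10A1 by 1.87 ± 0.20 and 1.62 ± 0.22. LIFR, a cytokine receptor, was 1.64 ± 0.20 higher at day 28 and 1.64 ± 0.23 higher at day 49. SLC27A2, a very long chain acyl-CoA synthetase, rose by 2.04 ± 0.29 at day 49, from 0.71 ± 0.87 (SD, n = 8) to 2.75 ± 0.20 (SD, n = 6). TRANK1, LOC616364, ZMAT1, FBXO21, SERPINA3-3, COL4A2 and SPINT2 rose by 1.34 to 1.76 at day 28 (a second SPINT2 element had the opposite sign and did not pass), and KDR, MBNL3, FBXO21, RASSF6 and LOC784007 by 1.54 to 1.79 at day 49.

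At day 28, of 45 ribosomal protein genes 20 fell and 1 rose (21 fell when adjusted over the list alone), with RPS27 at -0.70 ± 0.15 and RPL35 at -0.62 ± 0.14 (camera adjusted p = 1.95e-05, and 0.72 with an estimated correlation). Extracellular matrix genes fell in 6 of 18 cases and rose in 1 (8 and 1 when adjusted over the list alone), with MMP2 at -1.61 ± 0.24, COL6A1 at -1.51 ± 0.19 and FBLN1 at -1.32 ± 0.16 (adjusted p = 0.000135, and 0.569 with an estimated correlation). Stellate cell markers fell in 2 of 7 cases (3 when adjusted over the list alone), TAGLN (-0.81 ± 0.14) and THY1 (-0.45 ± 0.08), and glycolysis genes in 4 of 14 (6 when adjusted over the list alone), with ALDOA at -1.22 ± 0.21 while PGK1 rose (adjusted p = 0.00891 for both, and 0.569 and 0.645 with an estimated correlation). Endothelial markers rose in 4 of 8 cases (6 when adjusted over the list alone), with CDH5 at 1.02 ± 0.23 and TEK at 0.76 ± 0.20 (adjusted p = 0.00891, and 0.175 with an estimated correlation). A second PECAM1 element passed in the opposite direction. PECAM1 (0.49 ± 0.10), KDR (0.47 ± 0.15) and PGK1 (0.39 ± 0.10) were below 0 without centring, where the median of all elements was -0.61 and the endothelial median -0.11, still above the other elements.

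In the fixed metabolism set ACSL1, a long-chain acyl-CoA synthetase, rose by 0.66 ± 0.24 at day 28 in 7 of 8 cows (adjusted p = 0.0445), and PC fell by 0.67 on the log2 scale at day 49 (SE 0.15, 6 of 6 cows, adjusted p = 0.000954). CPT1A and SREBF1 did not pass on either day. At day 28, 849 elements were higher and 1012 lower, and at day 49, 1132 were higher and 1601 lower. Without centring 4821 elements passed at day 28 and 1319 at day 49, of which 0.954% and 12% were higher, so the balance of directions rested on the centring, and with liver in Cy5 alone 993 and 1640. Leaving out cow 7187 gave 1094 at day 28. On day 49 it leaves a single ad libitum cow, so no count is given for that day.

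Before calving, on the mean of days -30 and -14, no gene separated ad libitum from restricted cows by limma. The smallest p belonged to RARRES2, the adipokine chemerin, at 5.46 ± 0.10 (SD, n = 4) in restricted and 4.62 ± 0.20 (SD, n = 4) in ad libitum cows, a difference of -0.85 ± 0.13 (SE, adjusted p = 0.284). ETFB (-0.60), CD3E (-0.65), SERPING1 (-0.77) and QSOX1 (-0.73) followed in that direction. BCAP29 (0.76), SYNCRIP (0.72), CD2AP (0.65) and MAPK6 (0.73) lay in the other, as did WRAP53 with values in only 2 ad libitum cows and 1 restricted cow. The unadjusted p was under 0.05 for 1050 elements. In the limma fit by day it was under 0.05 for 77 elements on day -30 and for 1908 on day -14. The count was thus higher on day -14, a day of poorer orientation agreement. That fit holds a single spread per element for all days. The counts alone therefore do not show that the differences were larger on day -14.

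Before calving 7 of 26 gene lists passed with the preset correlation, 2 with an estimated correlation and 0 with fry. In 3 of 35 splits of the cows into 4 and 4 at least as many lists passed as in the real one (8 over complete elements, highest other 9). Of 10 complement genes 0 passed over all elements and 6 were lower in ad libitum cows when adjusted over the list alone, with C4A at -0.81 ± 0.17 and C1R at -0.54 ± 0.16 (camera adjusted p = 1.06e-06, and 0.0445 with an estimated correlation). Of 8 T and NK cell markers 3 were lower when adjusted over the list alone, including CD3E and CD3D (-0.55 ± 0.17), with adjusted p = 0.000267, and 0.0446 with an estimated correlation. Fatty acid oxidation genes were lower for 4 of 15 when adjusted over the list alone, ACAA1 at -0.88 ± 0.17 and ETFB among them (adjusted p = 0.00148, and 0.229 with an estimated correlation). The complement and fatty acid oxidation medians lay above the other elements by 0.05 and 0.11 under scale normalization. Ribosomal protein genes were lower for 17 of 45 and higher for 1 when adjusted over the list alone, with RPS2 at -0.63 ± 0.14 (adjusted p = 4.86e-11, and 0.229 with an estimated correlation). Of 16 chaperones 0 passed over all elements and 2 were higher when adjusted over the list alone, with HSP90AA1 at 0.66 ± 0.16 (adjusted p = 0.00148, and 0.422 with an estimated correlation). Of 12 NF-kB signalling genes and 9 growth hormone and IGF genes 0 passed over all elements and 1 each was lower when adjusted over the list alone, JUNB (-0.54 ± 0.13) and IGFBP3 (-0.76 ± 0.21), each with adjusted p = 0.041 and with 0.229 and 0.432 from an estimated correlation.

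After calving, on the mean of days 1, 14 and 28, many genes were higher in cows that had eaten freely before calving. P3H4, of the collagen hydroxylase family, was at 0.08 ± 0.16 (SD, n = 4) in ad libitum and -0.89 ± 0.10 (SD, n = 4) in restricted cows, a difference of 0.97 ± 0.11 (SE, adjusted p = 0.000965) seen in 16 of 16 pairs of cows. PLAUR, the urokinase receptor, PFDN5, UBE2C, ANXA8L1, TKDP4, ENAH, ADAMDEC1, FBXL6 and EIF3F differed by 0.90 to 0.95. Lower in ad libitum cows were AGPAT2, an acyltransferase of glycerolipid synthesis (-1.06 ± 0.27), the complement chain gene C1QC (-0.87 ± 0.24, adjusted p = 0.0432), the endothelial receptor TEK (-0.66 ± 0.15), and PRRC2B, ZNF217, IDUA, ATXN2, CNOT3, ARHGAP9 and LOC616364. Among these, AGPAT2, PRRC2B, ZNF217, IDUA, ATXN2 and ARHGAP9 had values in fewer than 4 cows of a diet. Another element of PFDN5, TKDP4, ENAH, PRRC2B, IDUA and ARHGAP9 had the opposite sign and did not pass. CPT1A, PC, ACSL1 and SREBF1 did not pass.

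Cell cycle genes were higher in ad libitum cows after calving for 3 of 17, UBE2C (0.94 ± 0.11), CDK2 (0.69 ± 0.10) and MCM4 (0.49 ± 0.11), and none was lower (3 when adjusted over the list alone). Camera gave this list adjusted p = 0.163 with the preset correlation, and 0.00635 with an estimated correlation. Ribosomal protein genes lay lower with 0 of 45 passing, also when adjusted over the list alone, RPS15A at -0.43 ± 0.12 (adjusted p = 0.0414, and 0.932 with an estimated correlation). Of 12 macrophage markers CD163 was higher (0.72 ± 0.11), while the other 11 had values below 0 and did not pass by the element that stood for them. A second CD14 element (-0.63 ± 0.17) and the C1QC element above, whose genes belong to the same list, did pass as lower. Of 8 endothelial markers TEK and KDR (-0.53 ± 0.14) were lower. The camera test passed for neither list (adjusted p = 0.414 and 0.405, and 0.932 for both with an estimated correlation). Second elements of CDK2 and KDR had the opposite sign and did not pass. The limma test passed for 844 of 8059 elements, 790 higher and 54 lower. No element passed on day 28 alone or with 2 within-group components as covariates, both chosen after seeing the data, 330 passed without centring and 433 with the liver in Cy3 alone. AGPAT2 and CNOT3 turned positive with the component covariates, and IDUA and ARHGAP9 with the liver in Cy3 alone.

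The 790 elements higher in ad libitum cows moved together. Their mean log2 ratio was -0.78 ± 0.95, -0.96 ± 0.49 and -0.84 ± 0.41 (SD, n = 4) in restricted cows on days -14, 1 and 14, and -0.34 ± 0.28, -0.04 ± 0.17 and 0.15 ± 0.07 (SD, n = 4) in ad libitum cows. Restricted cow 6877 stood apart on day -14 at 0.48, with the other restricted cows between -1.81 and -0.80. On days -65, -30, 28 and 49 the median diet difference of these elements was -0.0015, -0.06, 0.04 and 0.04. The days with a difference are those with poorer agreement of the dye orientations.

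**Figure D4:**
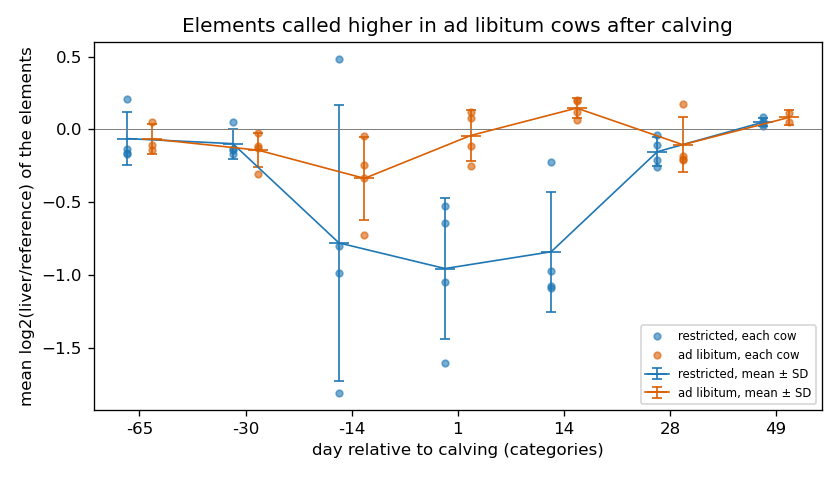
Mean log2 ratio of liver over reference (vertical axis) of the 790 elements called higher in ad libitum cows after calving, by day relative to calving (horizontal axis, spaced as categories). Points are cows, and horizontal marks with bars are the mean and SD of each diet. The diets separate on days 1 and 14, with restricted means of -0.96 and -0.84 against -0.04 and 0.15, and the elements were chosen for that difference.

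Day by day, elements passed on days -14, 1 and 14 and none passed on days -65, -30, 28 and 49. This fit holds a single spread per element for all days. Between restricted cows the mean of the 790 elements had SDs of 0.95, 0.49 and 0.41 on days -14, 1 and 14 and 0.10 on days -30 and 28. In ad libitum cows the SDs were 0.28, 0.17 and 0.07, and 0.12 and 0.19. The counts by day therefore depend on this shared spread. With array weights, which let it differ between cow-days, elements also passed on days -65, -30, 28 and 49, as listed below. For day -14 chance is not excluded, since 3 of 35 splits of the cows gave as many (509 over complete elements, highest other 1618). By size the largest increases were TMEM243 (2.30 ± 0.61, values in 2 restricted cows) and CDAN1 (1.98 ± 0.48, 3 ad libitum cows) on day -14 and HADHA (2.52 ± 0.73, 2 restricted cows) on day 1. CDAN1 had a value of 1.87 ± 0.48 already on day -65, which did not pass, so its day -14 value was close to the starting difference. On day -14 complement component C4A (-1.39 ± 0.25, adjusted p = 0.00199), the peroxisomal thiolase ACAA1 (-1.32 ± 0.30), SULT1A1 (-1.21 ± 0.32) and IGFBP3 (-1.18 ± 0.30, with 1 of its 2 other elements opposite in sign and not passing) were lower in ad libitum cows, and IDI1, of isoprenoid synthesis (1.43 ± 0.43), LGALS3 (1.13 ± 0.28) and HDAC2 (1.07 ± 0.21) were higher. On day 1, after HADHA, FBXL6, ANXA8L1, ENAH and LGALS3 were higher by 1.37 to 1.41, and YIPF4 (-1.66 ± 0.38) and the endoplasmic reticulum genes PDIA4 (-1.04 ± 0.30) and DDOST (-1.02 ± 0.23) were lower. On day 14 LOC619094 (1.68 ± 0.29) and MANF, an endoplasmic reticulum stress factor (1.47 ± 0.33), were higher, and FILIP1L (-2.46 ± 0.58), CNOT3 (-1.45 ± 0.36) and the macrophage receptor CD14 (-1.16 ± 0.31) were lower. PC was at -0.60 ± 0.19 on day -14 (adjusted p = 0.0515) and did not pass. On day -65 its diet difference had been 0.78 ± 0.21, opposite in sign, and did not pass either.

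The number higher and lower in ad libitum cows was 76 and 414 on day -14, 711 and 154 on day 1, and 935 and 295 on day 14. By limma, 285, 77, 93 and 48 elements had an unadjusted p under 0.05 on days -65, -30, 28 and 49. With the liver in Cy3 alone 0 elements passed on day -14 and 3 on day 1, and scale normalization and array weights left 71 and 22 on day -14. Each day tested alone gave 0, 0 and 515 elements on days -14, 1 and 14, and leaving out cow-days of low orientation agreement gave 224, 2 and 0. Without those cow-days the median difference of the 790 elements kept its direction while its error grew, going from 0.47 ± 0.27 to 0.43 ± 0.30 (SE) on day -14, from 0.93 ± 0.27 to 0.86 ± 0.36 on day 1 and from 1.01 ± 0.27 to 0.76 ± 0.36 on day 14. Those elements were chosen for a higher mean over days 1, 14 and 28 in ad libitum cows. The kept direction on days 1 and 14 therefore follows largely from that choice. Without centring 21, 0 and 717 elements passed on days -14, 1 and 14, and 4.76% and 97.8% of them were higher on days -14 and 14. Leaving out 1 cow moved the counts to between 51 and 1851 on day -14 (without 7050 and without 6877), between 3 and 1160 on day 1 (without 7187 and without 6877) and between 333 and 1468 on day 14 (without 7045 and without 6877).

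The diet by day test asked whether the time course differed between the diets. PA2G4, a growth regulator that binds RNA, had diet differences of 0.74 ± 0.14 and 0.84 ± 0.14 (SE) on days 1 and 14 and 0.10 ± 0.14 on day -30 (adjusted p = 0.0162). The glycolytic enzyme PKM differed by 0.97, 1.03 and 1.17 on days -14, 1 and 14 and by -0.05 on day -30 (adjusted p = 0.026). PGLS, of the pentose phosphate pathway, differed by -0.82 and -0.97 on days -14 and 1 and by 0.18 on day 14. LOC619094, AXL, TMEM214, HDAC2, AGPAT1, RAC1 and GANAB also passed. The limma interaction test passed for 65 elements, and 1467 had an unadjusted p under 0.05. Among 35 splits of the cows, 2 gave as many (66 over complete elements, highest other 126), so chance is not excluded. The count was 0 without centring, with scale normalization, without days -65 and 49, without the cow-days of low orientation agreement or without cow 6886 or 7045, and it was 20 without cow as a block, and 1036 without cow 6877. It was 1772 with array weights, 349 with component covariates and 106 with quantile normalization.

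No gene passed by limma for a diet difference in the change across calving, the mean of days 1, 14 and 28 minus that of days -30 and -14. BHLHE40, a transcription factor of the circadian system, had the smallest p among those that rose more in ad libitum cows (0.61 ± 0.10 against -0.15 ± 0.22, SD, n = 4 each, difference 0.76 ± 0.15, adjusted p = 0.503), followed by BCL3, SDC4, MAP1S and CEBPD. In the other direction lay RRP1B (-0.90 ± 0.14), LARP1B, ZNF622 (a single cow per diet), PRXL2A and TEK (-0.73 ± 0.15). Of 45 ribosomal protein genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.0396 with a higher median of 0.19, and adjusted p = 0.883 with an estimated correlation). An unadjusted p under 0.05 was reached by 715 of 8049 elements.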

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

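Groups of cows were examined for the named genes and for the agreement of the dye orientations. In 3 of the 74 groups a cow lay far from the others. Chance gives about 1 in 20, so this is no more than chance would give. For PRDX4, cow 6877 changed by -1.13 on the log2 scale from day -14 to day 1, while the nearest other cow was at 0.39. For HEYL, cow 7105 changed by -1.22 over the same days and the nearest cow by -0.64. For TEK, restricted cow 6877 had a mean of 3.36 on days 1, 14 and 28, and the nearest restricted cow 2.86.

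The diet difference varied between days for 65 elements by the limma interaction test. Adjusted p was 0.0162 for PA2G4, whose diet difference ran from -0.28 to 0.84 over the 7 days, 0.0244 for LOC619094 (-0.49 to 1.68) and 0.0244 for AXL (-0.34 to 0.90). It was 0.0256 for TMEM214 (-0.77 to 0.23) and 0.026 for PKM (-0.12 to 1.17), PGLS (-0.97 to 0.28) and HDAC2 (0.02 to 1.25). AGPAT1 reached 0.0265 (-0.09 to 1.13), RAC1 0.033 (-0.06 to 0.88) and GANAB 0.0335 (-0.77 to 0.22). Chance is not excluded for this count: among 35 splits of the cows, a test chosen after the result was seen, 2 gave as many, with 66 for the real split over elements with complete values and 126 for the highest other.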

How the results depend on the processing

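The component, agreement and loess settings, the fixed block, the low-agreement setting, the single days within diet means and most list counts were chosen after seeing the data. Of 289 counts of elements under other settings, 216 lay within 1.5 times the reported count, and among counts of lists 102 did and 43 did not. The rest follow as numbers of elements or lists past the test, and where no setting names a reason the cause was not tested. Fewer samples or elements enter where a dye, a day or a cow-day was left out. Signal over background was not analysed here.

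Without centring the counts were 0 for day 1 v day -14, 4821 for day 28 v day -14, 1319 for day 49 v day -14, 330 for diet after calving, 3 for the change by diet and 0 for the interaction. That setting further gave 21 for diet on day -14, 0 for diet on day 1, 717 for diet on day 14, 0 for the lactation contrast and 2 for lists for diet after calving, without centring. With quantile normalization the counts were 106 for the interaction, 291 for diet on day -14, 5 for lists for day 1 v day -14, 3 for lists for day 14 v day -14, 0 for lists for the change by diet and 8 for lists for the lactation contrast. With scale normalization the counts were 12 for day 1 v day -14, 0 for the interaction, 71 for diet on day -14, 5 for lists for day 1 v day -14, 11 for lists for day 28 v day -14, 5 for lists for the change by diet and 11 for lists for the lactation contrast. Over complete elements the count was 1 for diet on day -65. With liver in Cy3 alone the counts were 0 for day 1 v day -14, 3254 for day 28 v day -14, 433 for diet after calving, 4 for the interaction, 0 for diet on day -14 and 3 for diet on day 1. The others were 1 for diet on day 49, 3 for lists for day -14 v day -65, 6 for lists for day 1 v day -14, 2 for lists for day 14 v day -14 and 1 for lists for day 28 v day -14. With liver in Cy5 alone the counts were 993 for day 28 v day -14, 1640 for day 49 v day -14, 10 for the interaction, 3 for diet on day -65 and 658 for diet on day 14. There were also 1 for diet on day 49, 0 for the lactation contrast, 0 for lists for diet after calving and 0 for lists for the change by diet. Averaged per gene the count was 0 for lists for day 14 v day -14. With array weights the counts were 5497 for the day effect, 171 for day 1 v day -14, 1772 for the interaction, 12 for diet on day -65 and 9 for diet on day -30. That setting further gave 22 for diet on day -14, 19 for diet on day 28, 7 for diet on day 49, 998 for the lactation contrast and 0 for lists for diet after calving. Without days -65 and 49 the counts were 5 for day 1 v day -14, 0 for the interaction, 221 for diet on day -14 and 455 for diet on day 1. From days 1 and -14 alone the count was 5 for lists for the change by diet. With component covariates the counts were 119 for day 1 v day -14, 16 for day 14 v day -14, 1703 for day 49 v day -14, 0 for diet after calving, 349 for the interaction and 1 for diet on day -65. The others were 159 for diet on day 1, 757 for diet on day 14, 24 for the lactation contrast, 4 for lists for diet before calving, 8 for lists for diet after calving and 2 for lists for the change by diet. With the agreement covariate the counts were 1491 for the day effect, 1524 for day -14 v day -65, 2 for day 14 v day -14 and 1148 for day 28 v day -14. There were also 1559 for day 49 v day -14, 236 for diet on day -14, 0 for lists for diet after calving and 0 for lists for the change by diet. With loess the counts were 1 for day 14 v day -14, 36 for the interaction, 1 for diet on day -65 and 0 for the lactation contrast. That setting further gave 4 for lists for day 14 v day -14, 5 for lists for diet after calving, 0 for lists for the change by diet and 3 for lists for the lactation contrast. Without cow-days of low agreement the counts were 0 for day 1 v day -14, 0 for the interaction, 224 for diet on day -14, 2 for diet on day 1 and 0 for diet on day 14. On day 28 alone the counts were 0 for diet after calving and 6 for lists for diet after calving. On days 1 and 14 alone the count was 0 for lists for diet after calving. On day -30 alone the count was 3 for lists for diet before calving. With an estimated list correlation the counts were 0 for lists for day -14 v day -65, 0 for lists for day 1 v day -14, 0 for lists for day 14 v day -14, 0 for lists for day 28 v day -14, 2 for lists for diet before calving, 0 for lists for the change by diet and 0 for lists for the lactation contrast. With fry the counts were 13 for lists for day -14 v day -65, 3 for lists for day 1 v day -14, 0 for lists for day 14 v day -14, 0 for lists for diet before calving, 0 for lists for the change by diet and 1 for lists for the lactation contrast.

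Cow labels pair the samples, so the reported fits hold cow as a random block. Without that block the interaction count was 20, and with cow as a fixed block the lactation contrast gave 5. Tested on that day alone, with no block, the diet count was 0 on day -14, 0 on day 1 and 515 on day 14; these fits also drop all other days, so the move is not put down to the block. Among fits that changed only the treatment of cow as a block, no further count moved by over 1.5 times.

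Calls rose or fell together with the centring: without it, 98.4% of 3815 elements were higher for day -14 v day -65 (56.5% as reported), 0.954% for day 28 (45.6%) and 12% for day 49 (41.4%) v day -14, and 4.76% and 97.8% for diet on days -14 and 14 (15.5% and 76.0%). Quantile normalization gave 71.3% of 905 for diet on day 1 (82.2%) and 57.1% of 7 for the lactation contrast (77.8%). Loess gave 81.1% of 929 for diet after calving (93.6%) and 30.6% of 633 for diet on day -14 (15.5%).

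Leaving out 1 cow at a time, the counts ran as follows, with 1 cow named where several gave the same lowest or highest count. They were 2432 (without 7187) to 3608 (without 6877) for the day effect, 1459 (without 7187) to 2927 (without 6877) for day -14 v day -65, 3 (without 6952) to 96 (without 6877) for day 1 v day -14, 0 (without 6886) to 274 (without 6877) for day 14 v day -14 and 1094 (without 7187) to 2606 (without 6877) for day 28 v day -14. Next came 1128 (without 7187) to 3014 (without 6877) for day 49 v day -14, 0 for diet before calving, 647 (without 7105) to 953 (without 6877) for diet after calving, 0 for the change by diet and 0 (without 6886) to 1036 (without 6877) for the interaction. Then followed 0 (without 6886) to 1 (without 6877) for diet on day -65, 0 for diet on day -30, 51 (without 7050) to 1851 (without 6877) for diet on day -14, 3 (without 7187) to 1160 (without 6877) for diet on day 1 and 333 (without 7045) to 1468 (without 6877) for diet on day 14. The ranges went on with 0 for diet on day 28, a lowest of 0 (without 6877) for diet on day 49, 0 (without 6877) to 15 (without 7105) for the lactation contrast, 2 (without 6877) to 7 (without 6952) for lists for day -14 v day -65 and 5 (without 6952) to 12 (without 7105) for lists for day 1 v day -14. No highest count is given for diet on day 49, since that fit, without 7161, holds a single ad libitum cow on that day. For the same reason no lowest count is given for day 49 v day -14, from the fit without 7187. The lowest fit for the day effect, without 7187, has that limit too. After these came 0 (without 6952) to 2 (without 6886) for lists for day 14 v day -14, 5 (without 6877) to 6 (without 7045) for lists for day 28 v day -14, 5 (without 6952) to 7 (without 7187) for lists for diet before calving, 0 (without 6877) to 3 (without 7045) for lists for diet after calving and 0 (without 6886) to 2 (without 6877) for lists for the change by diet. Last was a lowest of 2 (without 6952) for lists for the lactation contrast. Its highest came from the fit without 7161, with a single ad libitum cow on day 49, and is not given.

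Among 26438 values of named genes under 33 settings, 24547 stayed on the same side of the threshold, 1423 no longer passed and 419 newly passed. The 24547 include values that passed in neither fit, and many named genes had not passed as reported. These figures therefore do not measure how stable the calls were. A further 49, called in the reported or the other setting, changed sign on the log2 scale. Changes of sign between values that passed in neither fit were not counted and lie among the 24547. Without centring, for day -14 v day -65, the values were IFI6 0.096, VSIG4 0.050, IDH3G 0.033, SDHA 0.083 and OAT 0.17. Without centring, for day 28 v day -14, the values were MCM4 -0.24, C1R -0.048, PECAM1 -0.13, KDR -0.15, ETFDH -0.059, PGK1 -0.24, CCT3 -0.35 and IFI6 -0.25. Without centring, for day 28 v day -14, the values were UQCRH -0.26, UQCRC1 -0.22, PSMD13 -0.012, PDHA1 -0.13, IDH3G -0.20 and AMT -0.35. With scale normalization, for day 28 v day -14, the values were MCM4 -0.015, C2 0.74, PGK1 -0.12, IGFBP3 0.31 and CCT3 -0.0095. With liver in Cy3 alone, for diet after calving, the values were IDUA 0.19 and ARHGAP9 0.40. With liver in Cy5 alone, for day -14 v day -65, the values were OAT 0.11. With liver in Cy5 alone, for day 28 v day -14, the values were PGK1 -0.015, UQCRH -0.064 and AMT -0.11. Averaged per gene, for day -14 v day -65, the values were MDH2 -0.20 and UBE2L3 -0.13. Averaged per gene, for day 28 v day -14, the values were IGFBP3 0.11. Averaged per gene, for diet after calving, the values were ACLY 0.36. With component covariates, for diet after calving, the values were AGPAT2 0.55, CNOT3 0.10, GLRX -0.21, POR -0.036, HSF1 -0.15, NDUFA9 -0.20, UBE2D2 -0.16 and PSMB3 -0.13. With component covariates, for diet after calving, the values were AGPAT1 -0.037. On day 28 alone, for diet after calving, the values were GLRX -0.061, HSF1 -0.0053, NDUFA9 -0.038, PSMB3 -0.046, GNLY -0.16 and AGPAT1 -0.011. Values without centring include the shift common to all elements, whose medians are given above. The cause was not tested for the other settings.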

Other observations

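Compared after seeing the data, days 28 and 49 against days -65 and -30 set lactation against the early dry period among days with close agreement of the dye orientations; 3 other day contrasts were looked at beside it. DBI, the acyl-CoA binding protein, was higher in lactation by 0.98 ± 0.20 (SE) in 8 of 8 cows (adjusted p = 0.0271), with ATP5MK, RPS25, RPS29, RPS15A, RPL39 and MRPS17 higher by 0.46 to 0.66 and CHD4 (-0.77 ± 0.15) and WWC1 (-0.53 ± 0.12) lower. Second elements of RPS15A and CHD4 had the opposite sign and did not pass. Of 45 ribosomal protein genes 4 rose and 20 rose when adjusted over the list alone (camera adjusted p = 4.07e-21, and 0.161 with an estimated correlation). Oxidative phosphorylation genes lay higher, 3 of 40 when adjusted over the list alone (adjusted p = 7.92e-09, and 0.198 with an estimated correlation), as did cholesterol synthesis genes, 4 of 7 with MSMO1 at 0.94 ± 0.26 (adjusted p = 0.00442, and 0.464 with an estimated correlation). Antioxidant and proteasome genes, with 0 of 23 and 0 of 27 past the test and also when adjusted over the list alone, had adjusted p = 0.00908 and 0.0113, and 0.384 and 0.464 with an estimated correlation. Over single elements 7 were higher and 2 lower, and 707 had an unadjusted p under 0.05 by limma. No element passed without centring, with the liver in Cy5 alone, with loess, or without cow 6877, 6886 or 7050, while 998 passed with array weights. The other contrasts gave 28 elements for day 28 against day -30, 9 for day -30 against day -65 and 1 for day 28 against day 49.

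Macrophage markers did not move together between day -65 and day -14: of 12, AIF1 (1.46 ± 0.20) and LAPTM5 (0.70 ± 0.19) rose and CD14 (-0.87 ± 0.20) and VSIG4 (-0.43 ± 0.16) fell. Without centring VSIG4 turned positive (0.050) but stayed below the median of all elements. Within the urea cycle list of 10 genes ASL rose (0.45 ± 0.10) while ASS1 (-0.63 ± 0.17) and OAT (-0.31 ± 0.12) fell. OAT turned positive with the liver in Cy5 alone (0.11) and without centring (0.17), where it stayed below the median of all elements. Of 40 oxidative phosphorylation genes 18 rose and 2 fell, led by NDUFS5 (0.79 ± 0.14), with camera adjusted p = 0.0786.

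All tests of explanations below, and the splits of the cows, were chosen after the results they concern had been seen.

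Days -14, 1 and 14 stood apart from the other 4 days. A single factor compressing every ratio towards 0 is argued against as the whole cause, because the ratio on the other days explained 17.4% of the variance of the change. The other tests scored cow-days on 2523 elements called between days -14 and -65, a choice that itself sets day -14 apart. Poorer orientation agreement stays open: the ratio of positions of well and less well agreeing cow-days was 1.01 (SE 0.353), but the former were 5 cow-days of 2 restricted cows counted as independent, and the limits for reading that ratio were revised after its value was known, which turned an excluded explanation into an open one. The mean also hides a spread among these 5. Cow 6952 on day 14, with the closest agreement (0.897), lay at 0.020, within the range of the other days. The rest of the 5 lay at 0.25 to 0.97. This single cow-day does not decide between the explanations. A set of arrays or labelling reactions made apart (23 of 24 cow-days beyond the range of the others, largely fixed by the choice of elements) and the weeks around calving (days -14 and 14 at 0.88 of the position of day 1) stay open and cannot be told apart, because the labels give no batch.

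The 790 elements higher in ad libitum cows after calving shifted together. A component shared by many elements within groups stays open: with scores on 2 such components as covariates the median difference per cow went from 0.65 ± 0.11 to 0.116 ± 0.27 (SE) and 0 passed, but in the fit of all cow-days it was still 0.19 ± 0.10 on day 1 and 0.24 ± 0.10 on day 14, where 71 and 262 of the 790 passed (159 and 757 of all elements), so part of the difference was left; the reading of this test was revised once these values were seen, from a supported explanation to an open one. The scores are projections of all values, so the setting removes any diet difference along those directions whatever its source, widens the error and leaves few degrees of freedom, and it was one of several corrections tried. Poorer orientation agreement is argued against as the whole cause only for a linear effect, since 680 elements passed with it as a linear covariate. Such a covariate cannot remove an effect particular to single samples, so that form stays open. Without the cow-days of low agreement 2 elements passed on day 1 and 0 on day 14, in fits with fewer cows. The feeding level stays open: the median difference was -0.0559 on day -30, within the feeding period, which neither requires nor rules out a later effect.

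Splitting the cows in the 34 other ways into 4 and 4, or exchanging days within cows, gave the following over elements with complete values. Chance is argued against for the diet count after calving (1 of 35 splits as high, real 861, highest other 0), on day 1 (1 of 35, real 872, highest other 32) and on day 14 (1 of 35, real 1234, highest other 942). A share of 1 of 35 is the lowest that these splits allow. It was not adjusted over the comparisons that were split, so chance is not ruled out. Chance is left open on day -14 (3 of 35, real 509), where another split called 1618, which points to a structure of the samples. On day -65 it is left open too (5 of 35, real 1, highest other 1). With a real count of 0 every split is at least as high, so nothing about chance follows before calving (35 of 35, highest other 1), for the change across calving (35 of 35, highest other 279), on day -30 (35 of 35, highest other 0) or on day 28 (35 of 35, highest other 0). Counts of gene lists were reached by 3 of 35 splits before calving (real 8, highest other 9), 29 of 35 after calving (real 1, highest other 10) and 27 of 35 for the change (real 1, highest other 6), so chance is not excluded for them.

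For days, chance is argued against for day -14 against day -65 (1 of 64 exchanges as high, real 2596, highest other 2068), day 49 against day -14 (1 of 32, real 2751, highest other 1908), and the test over 7 days (1 of 100, real 3502, highest other 1437). These are the lowest shares possible and were not adjusted over the comparisons. For days 28 and 49 against days -65 and -30 the share was 1 of 32 (real 9, highest other 2), the lowest possible, but the exchanges do not allow for choosing this contrast after 3 others had been looked at, so chance is left open. For day 28 against day -14 chance is argued against at 2 of 100 (real 1900), with the limit that another exchange called 1904, more than the real count, which points to a structure of the samples. It is left open for day 1 against day -14 (6 of 100, real 31), where an exchange that called 562 points to such a structure. For day 14 against day -14 the real count of 0 makes 100 of 100 certain, and the highest other was 1886. For gene lists it is not excluded for day -14 against day -65 (14 of 64, real 6, highest other 9), day 1 (6 of 100, real 10, highest other 13), day 14 (67 of 100, real 1, highest other 5) and day 28 (25 of 100, real 5, highest other 9) against day -14, or the lactation contrast (19 of 32, real 5, highest other 13).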
